A study of Homo sapiens with 6 samples.

How the data were processed

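RNA sequencing of total RNA from HepG2 cells was analysed in 6 libraries, 3 after control siRNA and 3 after FTO siRNA, with group and replicate number taken from the labels. RNA was extracted with Trizol and libraries were made by standard Illumina methods, per the labels' protocols; strand, read length, siRNA sequence, dose and time after transfection are not given in the sources used here. The authors deposited 1 table per library of raw counts per Ensembl gene. TopHat2 2.0.11, TopHat and HTSeq, and the genome builds hg19 and GRCh37, are named per the submitters' processing notes, without a role or an order. The settings of the counting, among them how reads that match several genes were treated and whether strand was used, are not given in the sources used here. Genes with near-identical copies, overlapping genes and antisense genes are therefore uncertain.

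Each file held 60483 gene identifiers with version numbers and no summary lines. Of these, 56753 matched GENCODE 29 by identifier and 37168 also by version. That release was used for symbols, gene types, chromosomes, transcript length and GC content, and no coordinates are given because its build differs from the one the notes name. Identifiers without a match held at most 0.052% of a library's counts. All 37 mitochondrial genes were listed at 0 in every library, so the list of mitochondrially encoded mRNAs was not tested. Total counts lay between 15713279 and 18390953 per library, which sets a floor of 3 counts per library at 0.163 to 0.191 CPM; floors and counting intervals (exact binomial, 95%) cover counting error only. No pair of libraries agreed within sampling noise: the chi-square of their counts over its degrees of freedom was 9.35 or more.

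Differential expression was tested with edgeR 4.0.16 in R 4.3.3 on the deposited counts. Genes were filtered with filterByExpr by group, scaled by TMM and tested with glmQLFit (legacy=FALSE) and glmQLFTest on an intercept and the group, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05 without a fold minimum. The standard error of a log2 fold change is its size over the square root of the F statistic. CPM values are TMM-scaled. The common biological coefficient of variation was 0.221. Where a gene had no count in one group, the fold is given as a bound over 3 counts per library of that group, and with 1 to 3 counts as a ratio with its counting interval.

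Before the data were examined, 52 gene lists were fixed. Those with at least 5 tested members, 50 of them, were tested with camera of limma 3.58.1 on log2 CPM (prior count 2) with a preset inter-gene correlation of 0.01, two-sided, adjusted over the lists. The list of endothelial markers had 3 tested members, too few for a set test; 1 rose, and 2 were higher and 1 lower when adjusted over the list alone. Members were counted at the threshold over all genes and adjusted over the list alone. The rule for named genes was fixed at the same time: FTO; then, among genes with a symbol, past the threshold, with an average log2 CPM of at least 1 and no overlap between groups, the 12 largest and the 12 smallest log2 fold changes; then up to 4 members with the smallest p-values in the direction of each called list, and up to 3 of each other list described. Genes named outside this rule are marked in the text. Some genes that meet the rule are not reported here.

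Reads shared between genes were gauged from the longest GENCODE 29 transcript of each gene as the share of its 50-base words that occur in another, non-overlapping gene. This measure, and the ranking of 10 genes per direction with an average log2 CPM of at least 4 and under 1% shared words, were chosen after the data were seen.

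The same steps were tested on simulated data for this comparison, with counts drawn for the 15025 tested genes and 200 of them changed. Of the genes changed 1.5-fold 1.49% were called, of those changed 2-fold 46.3% and of those changed 4-fold 92.4%, and 7 of 100 calls were unchanged genes. A list raised in the simulation was called, and camera called 0 of 49 unchanged lists. Each gene was drawn independently of the others there, so these list results do not test the preset inter-gene correlation.

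Alternatives planned before the data were examined were RLE, upper quartile and no composition factors; no filter, and at least 1 CPM in at least 3 libraries; DESeq2 1.42.0, limma-voom and edgeR's older quasi-likelihood method; a fold minimum of 1.2 (glmTreat); the replicate number as a block; each library left out; camera with an estimated correlation; and fry. Trends on GC content and length were removed from each library with lowess (span 0.3), and counts were repeated on protein-coding genes with under 1% shared words, both chosen after the data were seen. Where the text lists lost calls of single genes, it covers only fits with 1 library left out or with these trends removed. Losses under the other alternatives are given as totals. Tables were joined with Python 3.11.15 (pandas 2.3.3, numpy 2.4.6) and figures drawn with matplotlib 3.10.9.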

Results

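Gene expression was measured by RNA sequencing in HepG2, an established human liver cancer cell line, after transfection with an siRNA against FTO or with a control siRNA. FTO is a demethylase that removes the methyl group of N6-methyladenosine (m6A) from RNA, and the series set out to find the genes it regulates in this cancer. Each group held 3 libraries, numbered 1 to 3, and the values are raw counts per gene. Total counts were 15713279, 16488082 and 16739978 in controls 1, 2 and 3, and 16957438, 16407912 and 18390953 in FTO siRNA 1, 2 and 3. At this depth 3 counts in a library correspond to between 0.163 and 0.191 CPM, the usual scaling of counts to library size. This floor covers counting error only. Nothing in the labels says that the libraries of a group came from separate cultures. The p-values below measure the spread between these samples, which may be technical. CPM values are given as mean ± SD over 3 libraries and log2 fold changes, FTO siRNA against control siRNA, with their standard error.

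FTO (ENSG00000140718.17, chromosome 16) went from 39.2 ± 1.47 to 10.3 ± 4.69 CPM (n = 3 per group) and so to 26.3% of the control level. Its CPM values were 40.8, 37.96 and 38.8 in the controls and 11.2, 14.5 and 5.21 in the libraries labelled FTO siRNA. The targeted gene was thus lower in each of them than in every control. It fell by 1.93 ± 0.32 on the log2 scale (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.00932).

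After FTO siRNA, 7 of 21 genes of fatty acid synthesis and triglyceride storage fell and 3 rose, and 7 of 26 genes of cholesterol synthesis and uptake, 4 of 35 of DNA replication and 5 of 35 of mitosis fell. Among genes that rose were 16 of 28 of the NF-kB and cytokine response, 14 of 26 immediate early genes, 8 of 13 of antigen presentation, 9 of 27 of the integrated stress response and 10 of 26 matrix genes. With them rose 6 of 8 immune cell markers and 3 of 8 fibroblast markers. Camera called each of these lists with a preset inter-gene correlation, and every call was lost with an estimated one (adjusted p from 0.373 to 0.57). Splits of the libraries that mixed the groups also brought 9 to 23 list calls with the preset correlation. The lipid enzyme SCD fell by 1.31 ± 0.24, FASN fell by 1.13 ± 0.23 and the proliferation marker MKI67 fell by 1.30 ± 0.25 on the log2 scale. The lipid droplet gene CIDEC rose by 2.25 ± 0.23 and the cell cycle inhibitor CDKN1A by 2.30 ± 0.24. Of 15025 genes tested, 1132 were higher and 575 lower with FTO siRNA, or 11.4% of those tested, and 871 of the higher and 252 of the lower genes changed at least 2-fold. The 3 values of each group did not overlap for 5486 genes, or 36.5%, where chance gives 10% for 3 against 3.

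The counts of changed genes depended on single libraries. They came to 236 higher and 94 lower without control 1, to 287 and 106 without control 2, to 503 and 264 without control 3, to 751 and 324 without FTO siRNA 1 and to 883 and 513 without FTO siRNA 2. Without FTO siRNA 3 they were 2430 and 2152, a higher share of 53.03% where all 6 libraries gave 66.3%. In that fit 1705 of the 1707 genes called with all libraries were called again in the same direction. The first principal component, with 57.9% of the variance, separated the groups. The next, with 25.7%, set FTO siRNA 3 (52.7) apart from FTO siRNA 1 (-40.1) and FTO siRNA 2 (-22.7).

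**Figure D1:**
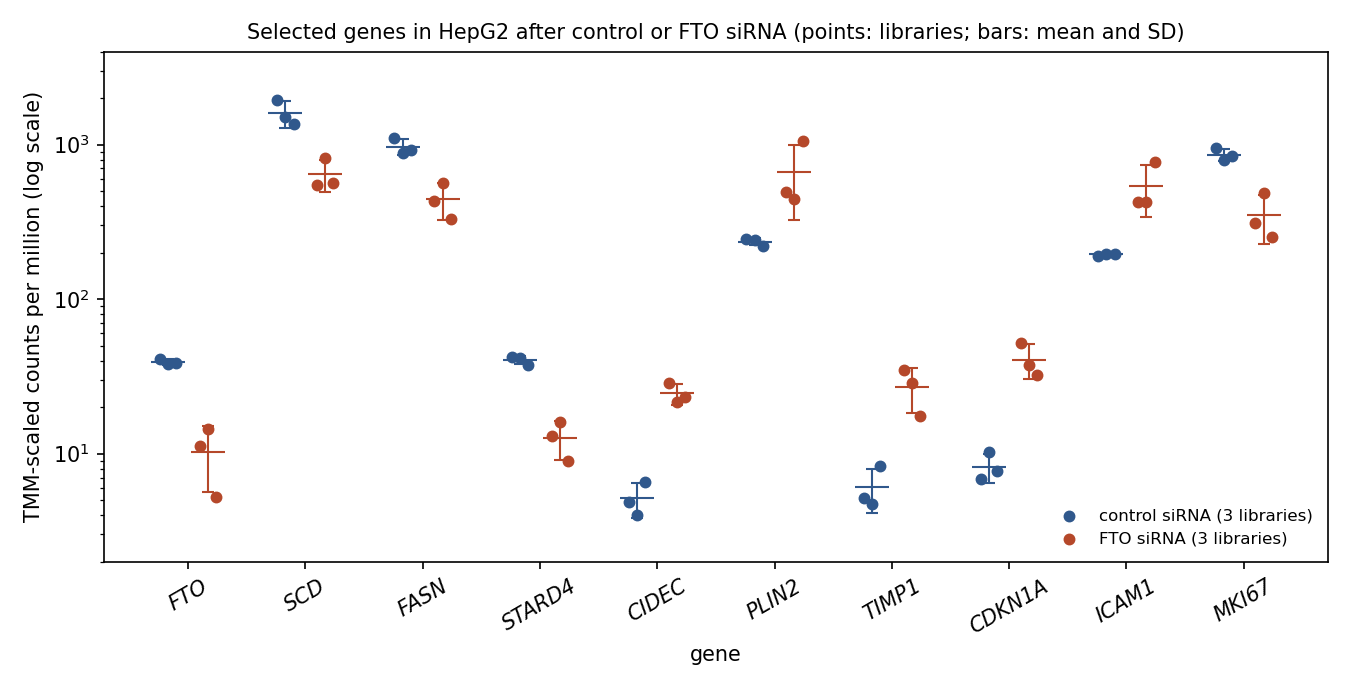
TMM-scaled CPM, on a log axis, of FTO and 9 other genes, for control siRNA (blue) and FTO siRNA (red). Points are libraries, bars are the mean and SD of 3. The 3 FTO siRNA values of FTO lie between 5.21 and 14.5 CPM, below the control values of 37.96 to 40.8 CPM. No gene shown has overlapping groups.

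Fatty acid synthesis fell at several of its enzymes. FADS1, a fatty acid desaturase, went from 297 ± 67.8 to 126 ± 22.6 CPM (adjusted p = 0.0108). SCD, which makes monounsaturated fatty acids, went from 1599 ± 311 to 646 ± 153 CPM (adjusted p = 0.0128). FASN, the fatty acid synthase, went from 971 ± 113 to 443 ± 118 CPM (adjusted p = 0.0172), and ACACA, which makes the malonyl-CoA it uses, from 172 ± 18 to 90.95 ± 20.1 CPM (adjusted p = 0.0182). Of the 21 measured members of the fatty acid synthesis and triglyceride storage list, 7 fell, 3 rose and 11 did not pass. Adjusted over the list alone, 8 were lower and 3 higher. The list's median log2 fold change was -0.40 (camera adjusted p = 0.0119; 0.373 with an estimated correlation). The 3 members that rose coat lipid droplets: CIDEC (5.16 to 24.5 CPM, adjusted p = 0.00217), PLIN2 (235 to 661 CPM, adjusted p = 0.0217) and PLIN3 (79.2 to 119 CPM, adjusted p = 0.0418), the last pair named after their values were seen. Refitted with 1 library left out or with trends on length and GC content removed, calls were lost for FADS1 and SCD without control 1 or control 2, ACACA without control 1, control 2 or FTO siRNA 1, FASN and PLIN2 without control 1, control 2 or control 3, PLIN3 without control 1, control 2, control 3, FTO siRNA 1 or FTO siRNA 2 and ACACA and PLIN3 with length and GC trends removed (highest adjusted p 0.214).

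Of 26 measured members of the cholesterol synthesis and uptake list, 7 fell and 19 did not pass. Adjusted over the list alone, 16 were lower and 1 higher. The median log2 fold change was -0.84 (camera adjusted p = 3.6e-08; 0.412 with an estimated correlation). STARD4, a sterol transport protein, fell by 1.68 ± 0.22 on the log2 scale (adjusted p = 0.00419). The sterol demethylase CYP51A1 fell by 1.11 ± 0.24 (adjusted p = 0.0217), although 21.1% of the words of its sequence occur in other genes. The call was lost for CYP51A1 without control 1, control 2, control 3 or FTO siRNA 1 (highest adjusted p 0.109).

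Many genes of NF-kB signalling and secreted cytokines rose. TNF, a proinflammatory cytokine, went from 1.8 ± 0.472 to 8.97 ± 1.75 CPM (adjusted p = 0.00337). SOCS3, a feedback inhibitor of cytokine signalling, went from 4.1 ± 1.33 to 27.2 ± 11.2 CPM (adjusted p = 0.00404), and RELB, an NF-kB subunit, from 23.4 ± 3.13 to 60.2 ± 11.05 CPM (adjusted p = 0.00488). The chemokine gene CCL2 had no count in any control library and 66 in the 3 FTO siRNA libraries, at least 6.93-fold higher over a floor of 3 counts per library. Of 28 measured members of the list, 16 rose and 12 did not pass, and 22 were higher when adjusted over the list alone. The median log2 fold change was 1.24, and the same with CCL2 at its lower bound (camera adjusted p = 1.2e-09; 0.373 with an estimated correlation). Immediate early genes, the transcription factors and phosphatases induced within minutes of a stimulus, rose at 14 of 26 members, and at 18 when adjusted over the list alone, with a median of 1.00 (camera adjusted p = 1.1e-07; 0.373 with an estimated correlation). Examples are DUSP5 (44.1 to 114 CPM, adjusted p = 0.00409), FOS (1.9 to 8.06 CPM, adjusted p = 0.00471), KLF4 (3.31 to 23.05 CPM, adjusted p = 0.00517) and JUNB (32.5 to 159 CPM, adjusted p = 0.00801). JUNB lost its call without control 1 (adjusted p = 0.0507).

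Antigen presentation genes rose in part: 8 of 13 measured members passed and 5 did not. When adjusted over the list alone 10 passed, and the median log2 fold change was 1.89 (camera adjusted p = 2e-08; 0.373 with an estimated correlation). The class I genes HLA-B (0.799 to 10.9 CPM), HLA-C (10.9 to 52.5 CPM) and HLA-E (21.5 to 89.97 CPM) had adjusted p-values of 0.00108, 0.00146 and 0.00173. These are related genes that share up to 5.76% of their 50-base words with other genes. In the type I interferon list 9 of 24 members rose and 15 did not pass. Adjusted over the list alone, 10 were higher and 3 lower, with a median of 0.81 (camera adjusted p = 0.00264; 0.429 with an estimated correlation). Among them were ISG15, a ubiquitin-like protein (9.13 to 25.4 CPM, adjusted p = 0.00318), IFI6 (1.48 to 9.1 CPM, adjusted p = 0.00471) and IFITM3, which restricts virus entry (20.04 to 55.4 CPM, adjusted p = 0.00488). Of the words of IFITM3, 20.3% occur in other genes.

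Transcripts of immune cells moved with the same groups of genes. Of the 8 immune cell markers with enough counts to test, 6 rose, 7 when adjusted over the list alone, with a median of 2.08 (camera adjusted p = 5.6e-06; 0.373 with an estimated correlation). Among them, PTPRC, the pan-leukocyte marker, had 2 counts over the 3 control libraries and 60 over the 3 FTO siRNA libraries, a ratio of 28.4 (95% counting interval 7.52 to 240), and NKG7, of natural killer cells, had the same 2 and 60 counts. CD3D, of T cells, went from 0.308 to 3.05 CPM (adjusted p = 0.00425) and CD74, the class II invariant chain, from 2.91 to 12.1 CPM (adjusted p = 0.00471). The constant-region genes of immunoglobulins and T cell receptors together had 0, 0 and 2 counts in the control libraries and 299, 346 and 336 in the FTO siRNA libraries.

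**Figure D2:**
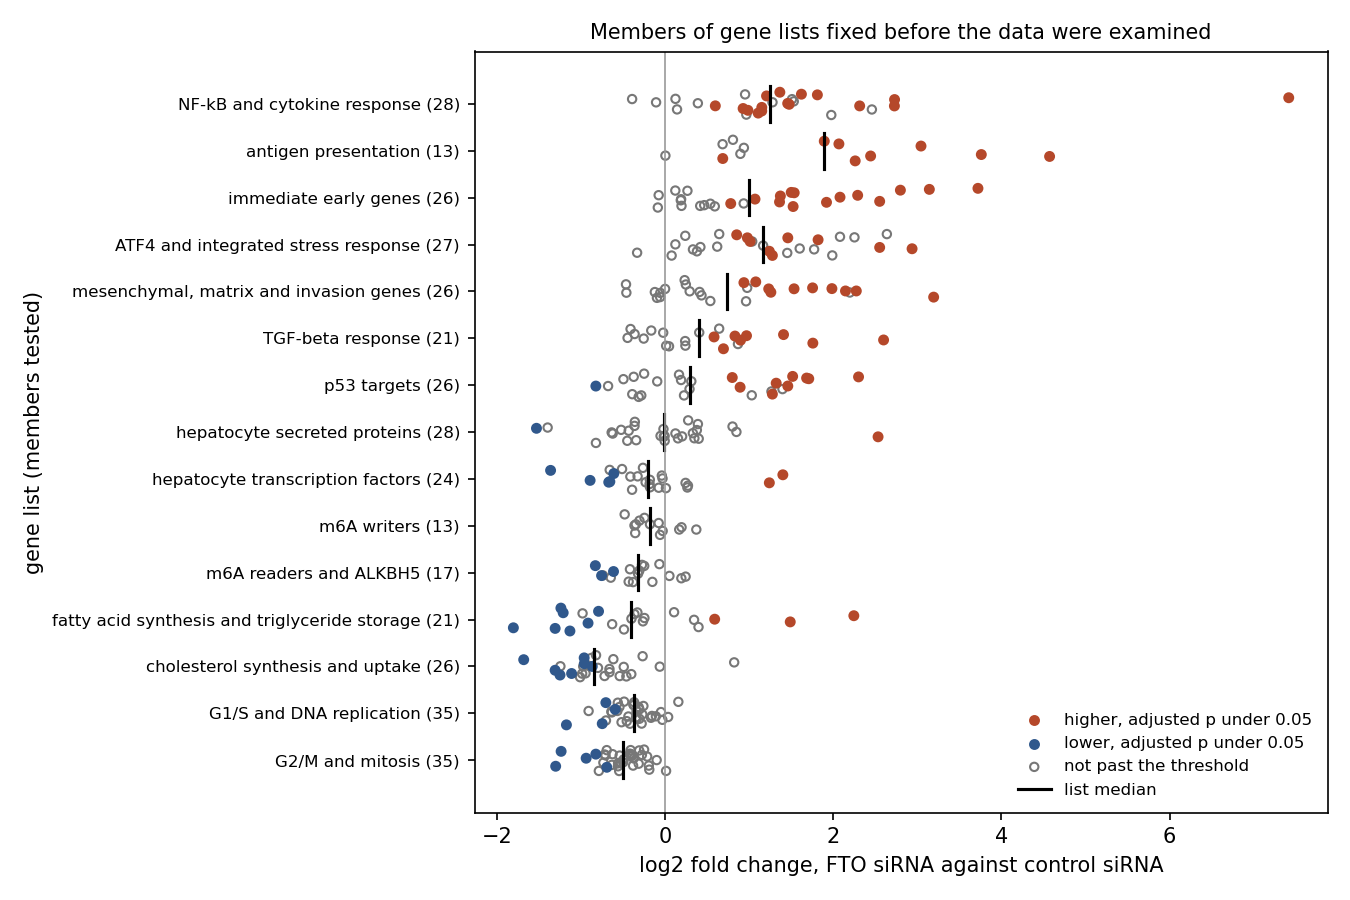
Log2 fold change (horizontal axis) of each tested member of 15 gene lists (vertical axis, with the number of tested members). Filled red and blue points passed an adjusted p of 0.05, open points did not, and black lines are list medians. The antigen presentation median lies at 1.89 and the cholesterol synthesis median at -0.84. The rightmost point, CCL2 in the NF-kB list, had no count in the controls, so its fitted fold is no measured size.

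Some genes of the integrated stress response rose: 9 of 27 measured members passed and 18 did not. Adjusted over the list alone 15 passed, with a median of 1.17 (camera adjusted p = 9.7e-05; 0.48 with an estimated correlation). CEBPB, a transcription factor, went from 30.5 ± 2.78 to 72.1 ± 15.1 CPM (adjusted p = 0.00628). PPP1R15A, the phosphatase subunit that ends the response, went from 171 ± 44.2 to 604 ± 202 CPM (adjusted p = 0.0078), and SLC3A2, a subunit of amino acid transporters, from 176 ± 20.8 to 347 ± 75.4 CPM (adjusted p = 0.0157). Chaperones of the unfolded protein response were not called as a list (21 members, median 0.04, camera adjusted p = 0.955). Of 26 measured p53 targets, 9 rose, 1 fell and 16 did not pass. With adjustment over the list alone 11 were higher and 3 lower, and the list was not called (camera adjusted p = 0.0736). It was called higher without FTO siRNA 3 (0.0397) and on genes with under 1% shared words (0.0151). Fry by direction called it higher too (adjusted p = 0.00575). Their smallest p-values belonged to the cell cycle inhibitor CDKN1A (8.23 to 40.6 CPM, adjusted p = 0.00217), to GADD45A (37.8 to 123 CPM, adjusted p = 0.00838) and to XPC, a DNA repair factor, which fell (57.2 to 32.3 CPM, adjusted p = 0.0115). Apoptosis regulators rose at 5 of 28 members, 9 when adjusted over the list alone, with a median of 0.29 (camera adjusted p = 0.0184; 0.373 with an estimated correlation). They were BIRC3, an inhibitor of apoptosis (34.6 to 106 CPM), the death receptors TNFRSF10A (14.2 to 27.2 CPM) and TNFRSF10B (109 to 202 CPM), the BH3-only protein BBC3 (4.2 to 13.5 CPM) and CFLAR, which blocks caspase 8 (77.8 to 118 CPM; named after its value was seen). Calls were lost for XPC without control 1 or control 2, TNFRSF10A without control 1, control 2 or FTO siRNA 2, SLC3A2 without control 1, control 2 or control 3, BBC3 without control 1, control 2, control 3 or FTO siRNA 1, TNFRSF10B without control 1, control 2, control 3 or FTO siRNA 2, CFLAR without control 1, control 2, control 3, FTO siRNA 1 or FTO siRNA 2 and TNFRSF10A and BBC3 with length and GC trends removed (highest adjusted p 0.201).

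Some proliferation genes fell. In the G2/M and mitosis list 5 of 35 members fell and 30 did not pass. With adjustment over the list alone 12 were lower, with a median of -0.50 (camera adjusted p = 3e-08; 0.48 with an estimated correlation). The kinetochore genes CENPE and CENPF went from 184 to 78.03 CPM and from 273 to 154 CPM (adjusted p = 0.00426 and 0.0123), MKI67 from 859 to 349 CPM (adjusted p = 0.015) and TOP2A, the topoisomerase of dividing cells, from 559.6 to 292 CPM (adjusted p = 0.0202). In the G1/S and DNA replication list 4 of 35 fell and 31 did not pass. With adjustment over the list alone 5 were lower, with a median of -0.37 (camera adjusted p = 6.2e-06; 0.57 with an estimated correlation). Among these 4 were the polymerase subunits POLA1 (76.7 to 47.1 CPM, adjusted p = 0.025) and POLE (191 to 127 CPM, adjusted p = 0.0278) and the helicase subunit MCM6 (142 to 84.5 CPM, adjusted p = 0.0461). Replication-dependent histones fell at 3 of 12 members, H1-2 (314 to 165 CPM), H4C8 (15.95 to 7.51 CPM) and H2BC12 (685 to 323 CPM, with 74.1% shared words). Adjusted over the list alone, 6 were lower and 1 higher, and the median was -0.38 (camera adjusted p = 0.0133; 0.438 with an estimated correlation). The histone list lost its call on genes with under 1% shared words (adjusted p = 0.0805). Calls were lost for MKI67 and H1-2 without control 1 or control 2, CENPF, TOP2A and H4C8 without control 1, control 2 or control 3, POLA1, POLE, MCM6 and H2BC12 without control 1, control 2, control 3 or FTO siRNA 1 and CENPF, TOP2A and POLE with length and GC trends removed (highest adjusted p 0.159).

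Genes of the mesenchymal state and the extracellular matrix rose at 10 of 26 measured members, and at 14 when adjusted over the list alone, with a median of 0.74 (camera adjusted p = 0.0003; 0.373 with an estimated correlation). SPARC, a matrix glycoprotein, went from 12.4 ± 1.79 to 42.1 ± 8.24 CPM (adjusted p = 0.00287), and ZEB2, a repressor of epithelial genes, from 1.36 ± 0.802 to 12.6 ± 2.83 CPM (adjusted p = 0.0035). TIMP1, a protease inhibitor, went from 6.07 ± 1.92 to 26.96 ± 8.65 CPM (adjusted p = 0.00581) and the integrin ITGA5 from 113 ± 3.69 to 269.5 ± 61.1 CPM (adjusted p = 0.00602). In the TGF-beta response list 8 of 21 rose, 10 when adjusted over the list alone, with a median of 0.41 (camera adjusted p = 0.0175; 0.373 with an estimated correlation). The ligands TGFB1 and TGFB2 went from 132 to 258 CPM and from 42.7 to 144 CPM (adjusted p = 0.0107 and 0.0153), and SMAD3 from 126 to 235 CPM (adjusted p = 0.0181). Of 21 hypoxia response genes 4 rose, also when adjusted over the list alone, with a median of 0.44 (camera adjusted p = 0.00515; 0.484 with an estimated correlation). Among them were the glucose transporter SLC2A1 (34.3 to 68.8 CPM), ANGPTL4, a lipase inhibitor (1.39 to 15.8 CPM), and EGLN3, a prolyl hydroxylase with 3 counts over the controls and 90 over the FTO siRNA libraries (ratio 28.4, interval 9.40 to 140). FTO siRNA 3 was the highest for both, with 31.7 CPM of ANGPTL4 against 9.36 and 6.36 in FTO siRNA 1 and 2, and without it their log2 fold changes came to 2.46 and 3.58 from 3.51 and 4.61. The epithelial junction and keratin list was not called (3 of 24 rose, camera adjusted p = 0.335), and CLDN4, a tight junction protein, rose from 1.34 to 10.9 CPM (adjusted p = 0.00233).

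Markers of other cells moved with these matrix genes. Of 8 measured fibroblast markers 3 rose, also when adjusted over the list alone, COL1A1 (14.9 to 42.2 CPM), COL1A2 (19.99 to 50.3 CPM) and TAGLN (60.3 ± 28.8 to 279 ± 187 CPM), with a list median of 0.62 (camera adjusted p = 0.0396; 0.373 with an estimated correlation). The groups overlapped for TAGLN, at 90.03 CPM in FTO siRNA 3 and 91.3 CPM in control 3. Of 6 markers of cervical and kidney lines 2 rose, KRT17 (0.203 to 2.54 CPM) and LIN28A (0.449 to 3.24 CPM), and 3 were higher when adjusted over the list alone, with a median of 1.00 (camera adjusted p = 0.0192, and 0.373 with an estimated correlation). LIN28A had 6, 2 and 14 counts in controls 1, 2 and 3. Its log2 fold change was 2.84, and 3.65 at the highest of the alternatives. Without FTO siRNA 3 the TGF-beta, hypoxia, fibroblast and cervical and kidney lists lost their calls (adjusted p = 0.0557, 0.0636, 0.0565 and 0.0597). The fibroblast list lost its call also without control 1 (0.0502) and without FTO siRNA 2 (0.0617). Single calls were lost for TGFB1, TGFB2, SLC2A1, ANGPTL4, COL1A1, KRT17 and LIN28A without control 1 or control 2, SMAD3 without control 1, control 2 or FTO siRNA 2, EGLN3 and COL1A2 without control 1, control 2 or control 3 and TAGLN without control 1, control 2, control 3, FTO siRNA 1 or FTO siRNA 2 (highest adjusted p 0.151).

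Among the proteins that write, read and erase m6A, some readers fell. IGF2BP3 (128 to 72.02 CPM, adjusted p = 0.0299), IGF2BP1 (396 to 234 CPM, adjusted p = 0.0441) and YTHDC2 (49.7 to 32.5 CPM, adjusted p = 0.048), all m6A-binding proteins, fell among 17 members of the readers and ALKBH5 list. When adjusted over the list alone 4 were lower, and the median was -0.32 (camera adjusted p = 0.00373; 0.373 with an estimated correlation). YTHDC2 was not called with total counts, upper quartile factors, either other filter, the replicate block or glmTreat. The list also holds the other known m6A demethylase of mRNA, ALKBH5 (109.6 to 92.3 CPM, adjusted p = 0.67; named after its value was seen), which did not pass. Its lower mean came from FTO siRNA 3 (42.97 CPM), and without that library its log2 fold change was 0.07. Of 13 m6A writers, edgeR called 0, with 1 higher and 2 lower at an unadjusted p under 0.05, and DESeq2 and limma-voom called 0 too. The list was not called (median -0.18, camera adjusted p = 0.205), and METTL3, the catalytic subunit, went from 75 to 58.3 CPM (adjusted p = 0.249; named after its value was seen). Among 22 genes named as FTO targets in earlier work, 3 rose and 3 fell. When adjusted over the list alone 3 were higher and 5 lower, without a call of the list (camera adjusted p = 0.997). Its smallest p-values were those of CIDEC and ASB2, a ubiquitin ligase subunit (1.85 to 9.87 CPM, adjusted p = 0.0114), which rose, and SCD, which fell. The others were MYC, which rose (155 to 267 CPM), and FASN and CEBPA, which fell, all named after their values were seen. Around the FTO gene itself, RBL2, a pocket protein of the retinoblastoma family, fell (31.7 to 17.1 CPM, adjusted p = 0.0163) and the other 5 measured neighbours did not pass, while 2 were lower when adjusted over the list alone (list camera adjusted p = 0.196). Calls were lost for ASB2 without control 2, RBL2, SCD and CEBPA without control 1 or control 2, IGF2BP3, MYC and FASN without control 1, control 2 or control 3, IGF2BP1 without control 1, control 2, control 3 or FTO siRNA 1, YTHDC2 without control 1, control 2, control 3, FTO siRNA 1 or FTO siRNA 2 and IGF2BP1 and YTHDC2 with length and GC trends removed (highest adjusted p 0.197).

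RNA processing lists were called lower, with small medians. Of 33 splicing factors 3 fell, also when adjusted over the list alone, with a median of -0.24 (camera adjusted p = 0.00238; 0.373 with an estimated correlation). They were PRPF8, a core spliceosome protein (636 to 363 CPM), HNRNPH1 (967 to 621 CPM) and U2AF1 (4.75 to 1.7 CPM), of whose words 98.1% occur in another gene. Of 27 genes of nonsense-mediated and general RNA decay 2 fell, DCP2, the decapping enzyme (65.9 to 36.6 CPM), and CNOT6, a deadenylase (97.2 to 64.3 CPM), and 1 when adjusted over the list alone, with a median of -0.11 (camera adjusted p = 0.0445; 0.429 with an estimated correlation). This call was lost without control 1 (adjusted p = 0.0502) and without FTO siRNA 1 (0.0988), with a filter of 1 CPM in 3 libraries (0.0563), on genes with under 1% shared words (0.0805) and with length and GC trends removed (0.155). Of 13 genes of the siRNA machinery, which both siRNAs use, edgeR called 0 (7 were lower at an unadjusted p under 0.05, DESeq2 called 1 lower and limma-voom 0), and the median was -0.38 (camera adjusted p = 0.00554; 0.373 with an estimated correlation). Single calls were lost for DCP2 without control 2, U2AF1 without control 1, control 2 or control 3, PRPF8 and CNOT6 without control 1, control 2, control 3 or FTO siRNA 1, HNRNPH1 without control 1, control 2, control 3 or FTO siRNA 2 and PRPF8, HNRNPH1 and CNOT6 with length and GC trends removed (highest adjusted p 0.281).

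Hepatocyte genes moved in both directions. Of 28 measured secreted proteins of the hepatocyte 1 rose and 1 fell, also when adjusted over the list alone, and the list was not called (median -0.01, camera adjusted p = 0.49), though it was called lower without control 3 (0.0387). ITIH2, an inhibitor subunit that binds hyaluronan, went from 561 ± 152 to 194 ± 61.6 CPM (adjusted p = 0.0125) and APOA4, an apolipoprotein, from 2.93 ± 1.11 to 16.9 ± 11.4 CPM (adjusted p = 0.0191). APOA4 stood at 14.2, 7.04 and 29.4 CPM in FTO siRNA 1, 2 and 3. Its log2 fold change was 2.53, and 1.83 at the lowest of the alternatives. APOB, the structural protein of VLDL, went from 6889.9 ± 1620.2 to 2616 ± 1344 CPM and did not pass (adjusted p = 0.065). It passed under 4 of the alternatives, and with 1 library left out its edgeR adjusted p lay between 0.00172 and 0.204. Of 24 hepatocyte transcription factors 2 rose and 5 fell, also when adjusted over the list alone (camera adjusted p = 0.0538), among them CEBPD (22.2 to 58.6 CPM, adjusted p = 0.00425) and CEBPB, which rose, and ONECUT1 (43.2 to 16.8 CPM, adjusted p = 0.0198), which fell. The list of transcription factors was not called, but it was called lower without control 3 (0.0220), without FTO siRNA 3 (0.0177), on genes with under 1% shared words (0.0270) and with length and GC trends removed (0.0104). In the amino acid catabolism and urea cycle list 1 of 19 members rose and 3 fell, also when adjusted over the list alone (camera adjusted p = 0.49). They include HPD, of tyrosine breakdown (0.696 to 3.92 CPM, adjusted p = 0.0073), and GLUD1, the glutamate dehydrogenase, which shares 25.8% of its words with other genes (464 to 194 CPM, adjusted p = 0.00649). In the fatty acid oxidation and ketogenesis list 2 of 23 rose and 1 fell, also when adjusted over the list alone (camera adjusted p = 0.821). ANGPTL4 and CPT1A, which carries fatty acids into mitochondria (7.45 to 22.9 CPM, adjusted p = 0.0212), rose, and EHHADH, a peroxisomal enzyme, fell (30.5 to 12.9 CPM, adjusted p = 0.00703). Calls were lost for HPD without control 1, ITIH2 without control 1 or control 2, ONECUT1 without control 1, control 2 or FTO siRNA 2 and APOA4 and CPT1A without control 1, control 2 or control 3 (highest adjusted p 0.101).

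Among called genes with an average log2 CPM of at least 1 and non-overlapping groups, the 12 largest increases by fold were in IGKC, PAEP, SBK3, RPL10P9, CCL5, MEIS3, CRABP2, EBI3, ETS1, IL11, WNT9A and RASGRF1. For some of them FTO siRNA 3 held most of the counts. In FTO siRNA 1, 2 and 3, MEIS3 had 26, 17 and 207 counts and SBK3 28, 31 and 157. WNT9A had 33, 36 and 186 and IL11 298, 222 and 803. IGKC, the constant region of the kappa light chain, had no count in the controls and 291 in the FTO siRNA libraries, at least 30.6-fold higher over a floor of 3 counts per library. PAEP, a secreted lipocalin, had 2 and 200 counts, a ratio of 94.6 (interval 25.8 to 786). Its control counts were 2, 0 and 0 in controls 1, 2 and 3, so the size of the ratio rests on control 1. CRABP2, a retinoic acid carrier, rose by 4.52 ± 0.41, the transcription factor ETS1 by 4.35 ± 0.46, the cytokine IL11 by 4.31 ± 0.63 and the chemokine CCL5 by 5.17 ± 0.55 on the log2 scale. Without control 3 the log2 fold changes of ETS1, IL11 and CCL5 came to 5.38, 5.26 and 6.66. CCL5 had 0, 1 and 4 counts in controls 1, 2 and 3 and 62, 75 and 66 in FTO siRNA 1, 2 and 3. It shares 17.2% of its words with other genes. Whether immune-cell RNA brought part of the rise of CCL5 or ETS1 was not tested. The 12 largest decreases under the same limits were in H4C15, BZW1P2, EIF3CL, TECRP1, FABP5P7, SRP9P1, RAP1BL, CKS1BP3, RAMACL, TMEM183BP, CTXND1 and RAC1P2. Of these, EIF3CL, a copy of an initiation factor subunit, fell by 4.17 ± 0.30 and BZW1P2, a processed pseudogene, fell by 4.52 ± 0.24. They share 64.7% and 99.6% of their words with other genes, so their counts depend on how reads were assigned between copies. The pseudogene TECRP1 and CTXND1 share 0% of their words. The measure covers exact words of the longest transcript of each gene only. It does not show whether reads of TECRP1 could match another gene through other transcripts or with mismatches. Of 741 tested pseudogenes 55 were higher and 92 lower, and they made up 9 of the 10 smallest p-values. Calls were lost for CTXND1 without control 1, SBK3 without control 1 or control 2 and MEIS3 and WNT9A without control 1, control 2 or control 3 (highest adjusted p 0.106).

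**Figure D3:**
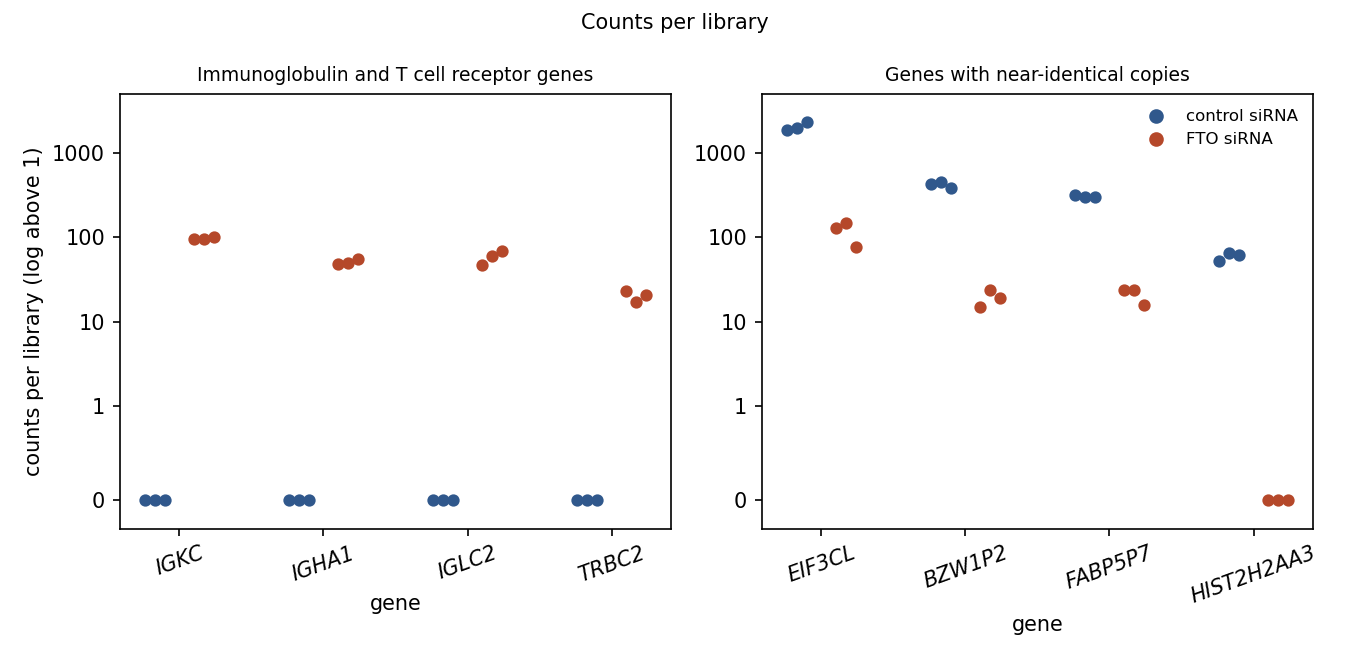
Counts per library, on an axis that is logarithmic above 1, for 4 constant-region genes of immunoglobulins and a T cell receptor (left) and 4 genes with near-identical copies (right), for control siRNA (blue) and FTO siRNA (red). Points are libraries. IGKC lies at 95 to 100 counts in the FTO siRNA libraries and at 0 in the controls.

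Because of these copies, abundant protein-coding genes with under 1% shared words were also ranked, a choice made after the data were seen. Among the 10 largest increases were CNN1, a smooth muscle calponin (4.77 ± 2.8 to 48.9 ± 21.2 CPM, adjusted p = 0.00579), CREB3L1, a membrane-bound transcription factor (6.18 ± 2.3 to 37.1 ± 7.25 CPM, adjusted p = 0.00246), and ARHGDIB, a regulator of small GTPases (4.82 ± 2.27 to 28.7 ± 7.22 CPM, adjusted p = 0.00488). Among the 10 largest decreases were ATP2B2, a plasma membrane calcium pump (103 ± 42.05 to 19.8 ± 10.6 CPM, adjusted p = 0.0106), SPTLC3, a subunit of serine palmitoyltransferase (32.9 ± 10.8 to 7.18 ± 2.93 CPM, adjusted p = 0.00922), FTO, STARD4 and MBNL3, a splicing regulator (380.3 ± 59.2 to 129 ± 26.4 CPM, adjusted p = 0.00381).

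Other lists that were not called include gluconeogenesis and glycogen (camera adjusted p = 0.141), nuclear genes of oxidative phosphorylation (0.991), coagulation and complement (0.469, 4 of 30 higher and 1 lower), bile acid, drug and steroid metabolism (0.589, 2 of 22 higher) and fetal liver markers (0.439, 1 of 17 higher and 3 lower). Wnt targets (0.376, 2 of 14 higher), YAP and TEAD targets (0.532, 1 of 17 higher) and D cyclins with their regulators (0.626, 2 of 19 higher and 2 lower) were not called either. Leaving out 1 library brought calls of gluconeogenesis and glycogen (higher without FTO siRNA 1, 0.0442), coagulation and complement (higher without FTO siRNA 2, 0.0241) and oxidative phosphorylation (higher without FTO siRNA 3, 0.0108). Of the 25 lists not called, 12 were called by camera under at least 1 alternative, and by fry 14 for change in either direction and 2 by direction. These 2 were p53 targets and metallothioneins, both higher. In all, 25 of 50 tested lists were called, 15 higher and 10 lower, and 18 of these in each of the 6 fits that left out a library. With an estimated correlation camera called 0, with 2 lists at an unadjusted p under 0.05, and fry called 17 by direction. Among the called lists, fry by direction did not pass fatty acid synthesis (adjusted p = 0.0505), cholesterol synthesis (0.0579), mitosis (0.0974) or DNA replication (0.229). It also did not pass the integrated stress response (0.0974), histones (0.0549), RNA decay (0.0579), hypoxia (0.0846), ribosomal proteins (0.499) or heat shock chaperones (0.515).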

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

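The removal of GC and length trends and the restriction to genes with under 1% shared words were chosen after the data were seen. FTO was lower and past the threshold under every alternative run, with log2 fold changes between -2.29 and -1.63 and adjusted p-values from 9e-08 to 0.046. The counts of genes stayed within 1.5 times of 1132 higher and 575 lower with other scaling factors, filters, limma-voom, the older quasi-likelihood method and the trends removed (994 to 1196 higher, 507 to 634 lower), and no scaling moved the median gene by over 0.05 on the log2 scale. DESeq2 called 924 lower genes, glmTreat with a fold minimum of 1.2 called 315 lower, and protein-coding genes with under 1% shared words gave 753 higher, from 9585 genes tested. Leaving out 1 library gave between 236 and 2430 higher and between 94 and 2152 lower genes, the lowest without control 1 and the highest without FTO siRNA 3. The cause was not tested for DESeq2 or for single libraries; the fold minimum and the smaller gene set lower a count by construction. With the replicate number as a block, 736 genes were higher and 305 lower, and 24 of the 25 called lists were called again in the same direction, all but RNA decay (adjusted p = 0.0508), and p53 targets were called as well (0.0462). The labels do not say that a number pairs samples, and deviations from the group means of same-numbered libraries correlated at -0.14, -0.06 and -0.25 across genes, so the numbers were not treated as pairs. Camera called 25 of 50 lists with the preset correlation and 0 with an estimated one (2 at an unadjusted p under 0.05, smallest adjusted p 0.373), while fry called 17 by direction and 35 for change in either direction. Lists called under the other alternatives numbered 23 to 28. Over 143 other genes recomputed, 140 of them called, 2530 results under an alternative held 2242 that were unchanged, 284 lost calls, 4 gained calls (all of APOB) and 0 reversals. Of the 140 calls, 72 were lost without control 1, 70 without control 2, 39 without control 3, 19 without FTO siRNA 1, 13 without FTO siRNA 2 and 0 without FTO siRNA 3. The block ended 17, glmTreat 19, the removal of trends 17, no filter 6, limma-voom 5 and total counts without factors 4 of these calls. Small changes can be missed: in the simulation, with 3 libraries per group and 200 genes changed, 1.49% of genes changed 1.5-fold were called. The data held 1707 called genes, which changes the adjustment over genes, so this share need not hold for them.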

Other observations

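The tests of whether immune-cell RNA brought the higher NF-kB and antigen presentation values, and of a batch that runs with the groups, were chosen after the result was seen.

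Several groups outside the main themes also moved. Autophagy and lysosome genes rose at 6 of 30 measured members, also when adjusted over the list alone, with a median log2 fold change of 0.27 (camera adjusted p = 0.00303; 0.376 with an estimated correlation). They include the lysosomal proteases CTSL (103 ± 3.43 to 207 ± 26.6 CPM, adjusted p = 0.00576) and CTSB (311 ± 8.15 to 516 ± 28.4 CPM, adjusted p = 0.0157) and GABARAPL1, an autophagosome protein (55.5 ± 10.1 to 111 ± 10.4 CPM, adjusted p = 0.0101). Nuclear noncoding RNAs rose at 3 of 9 members, 5 when adjusted over the list alone, with a median of 0.52 (camera adjusted p = 0.0192; 0.438 with an estimated correlation). MALAT1, a nuclear speckle RNA, went from 71.3 ± 12.5 to 209 ± 41.05 CPM (adjusted p = 0.00415). Of 54 cytosolic ribosomal proteins RPL26 alone rose over all genes tested (11.3 to 19.5 CPM, with 17.7% shared words), and edgeR called 0 when adjusted over the list alone. Their median was 0.35 (camera adjusted p = 0.00373; 0.808 with an estimated correlation), and the call was lost without FTO siRNA 1 (adjusted p = 0.463) and on genes with under 1% shared words (adjusted p = 0.264). Calls of single genes were lost for CTSL without control 1, GABARAPL1 without control 1 or control 2, CTSB without control 1, control 2 or control 3 and RPL26 without control 1, control 2, control 3, FTO siRNA 1 or FTO siRNA 2 (highest adjusted p 0.16).

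Glycolysis was not called as a list (4 of 23 rose and 1 fell, also when adjusted over the list alone; camera adjusted p = 0.208, and 0.0441 on genes with under 1% shared words). Of its members the hexokinase HK1 rose from 0.593 ± 0.166 to 4.85 ± 0.128 CPM (adjusted p = 0.00164) and the enolase ENO2 from 2.72 ± 1.02 to 16.3 ± 2.87 CPM (adjusted p = 0.00283). Metallothioneins, which bind zinc and copper, rose at 5 of 12 members of their list, also when adjusted over the list alone, among them MT1X (3.81 to 7.51 CPM, adjusted p = 0.0283) and MT2A (36.2 to 93.5 CPM, adjusted p = 0.0461; named after its value was seen), without a call of the list (camera adjusted p = 0.0627). That list was called higher without control 2 (0.0265), without FTO siRNA 1 (0.0399) and with length and GC trends removed (0.0393). Fry by direction called it higher too (adjusted p = 0.0288). Of 25 NRF2 targets 3 rose, 5 when adjusted over the list alone, among them HMOX1, the heme oxygenase (50.2 to 101 CPM, adjusted p = 0.0157; list camera adjusted p = 0.0907, and 0.00026 without FTO siRNA 3, called higher). Heat shock chaperones were called lower, with 1 of 20 members higher and 1 lower, also when adjusted over the list alone, and a median of -0.31 (camera adjusted p = 0.0267; 0.773 with an estimated correlation). HSPA4L fell (31.3 to 17.3 CPM) and HSPB1, a small heat shock protein, rose (71.2 to 120.2 CPM; named after its value was seen), and the list lost its call without control 3 (adjusted p = 0.0900) or FTO siRNA 3 (adjusted p = 0.705) and on genes with under 1% shared words (adjusted p = 0.378). Calls of single genes were lost for HMOX1 and HSPA4L without control 1, control 2 or control 3, HSPB1 without control 1, control 2, control 3 or FTO siRNA 1, MT2A without control 1, control 3, FTO siRNA 1 or FTO siRNA 2, MT1X without control 1, control 2, control 3, FTO siRNA 1 or FTO siRNA 2 and MT1X, MT2A, HSPA4L and HSPB1 with length and GC trends removed (highest adjusted p 0.183). The proteasome, mitochondrial ribosome, ribosome biogenesis and translation lists were not called (camera adjusted p = 0.376, 0.364, 0.376 and 0.83). Without FTO siRNA 1 the first 3 were called lower (0.00403, 0.0122 and 0.0498), without FTO siRNA 3 the proteasome was called higher (0.0389), and with trends removed the mitochondrial ribosome was called lower (0.0393).

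Some pseudogenes and duplicated genes changed by large folds. Of 416 genes with at least 50% of their 50-base words in another gene, 25.5% were called (20 higher, 86 lower), 1.88 times the 13.5% of genes with under 1% shared words at matched abundance (95% interval 1.57 to 2.22), which argues for reads having been assigned differently between copies in the 2 groups. HIST2H2AA3, named after its values were seen, shares 100% of its words and had 52, 65 and 62 counts in the controls and 0 in each FTO siRNA library, at least 21.03-fold lower over a floor of 3 counts per library. Pseudogenes with under 10% shared words were called 0.224 times as often as those with at least 50% (6.94% against 30.96%; interval 0.126 to 0.347), which argues against a change in the pseudogenes' own transcripts as the whole explanation. What made the assignment differ, such as reads or settings that differed between the groups, stays open.

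Constant-region genes of immunoglobulins and T cell receptors together had 299 or more counts in each FTO siRNA library and at most 2 in a control, while some immune cell markers, such as CD74, had counts in every control. RNA or reads of other human cells is a candidate source, since 34 of 243 immunoglobulin and T cell receptor variable genes, which are expressed after rearrangement in lymphocytes, had a count only in FTO siRNA libraries. The variable genes do not decide on induction in the HepG2 cells. Together they had 48 or more counts in each FTO siRNA library but also 33, 29 and 42 in controls 1, 2 and 3. Fewer of these genes had a count in the controls (5, 5 and 7, against 20, 17 and 22 in FTO siRNA 1, 2 and 3). Over all genes, 53 had no count in the controls and at least 5 in every FTO siRNA library, against 1 the other way. The source of these 53 was not tested. The called members of the NF-kB list rose by a median of 46.1 CPM (interval 13.4 to 159) and those of the antigen presentation list by 25.8 CPM (interval 1.09 to 87.7), where the immune cell markers without LYZ rose by 19.0 CPM in sum and IGKC reached 5.63 CPM. Of the called members 11 of 16 and 4 of 8 each rose by more than this sum, but both intervals include it. These intervals are for a median over different genes, so they do not measure the error in the rise of a single gene. How much of these lists came with immune-cell RNA stays open, and RNA of other foreign cells was not tested against them.

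Of the 50 tested lists 25 were called, and the libraries differed in length and GC trends: the shortest 20% of abundant protein-coding genes stood 0.80 log2 units above the longest 20% in FTO siRNA 1, 0.32 in FTO siRNA 2 and -0.01 in FTO siRNA 3, and the GC-richest 20% stood above the GC-poorest 20% by 0.57, 0.30 and 0.06. With these trends removed, 24 of the 25 called lists were called again in the same direction, which argues against the trends as the whole cause; the lost one was nonsense-mediated and RNA decay (adjusted p = 0.155). A library or sequencing batch that runs with the groups cannot be told apart from the siRNA, since the labels give no batch that crosses them. The variable-gene counts, in which 0 libraries lacked their group's mark, do not decide it, because the idea came from such counts and they were close (42 in control 3, 48 in FTO siRNA 2). Constant-region counts did separate all libraries by group: 0, 0 and 2 in the controls, and 299, 346 and 336 with FTO siRNA. HIST2H2AA3 did so too, with 52, 65 and 62 counts in the controls and 0 in each FTO siRNA library. Such marks run with the groups, so they do not separate a batch from the siRNA. An effect of FTO depletion, or of the FTO siRNA on other transcripts, stays open and was not tested separately.

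The 6 libraries allow 10 splits into 3 and 3, too few for a share under 0.05. Each split other than the real one mixed control and FTO siRNA libraries. The difference between the real groups therefore widened the spread within its groups and made gene calls unlikely beforehand. For both directions 1 of the 10, the real one, gave as many genes (1132 higher and 575 lower), and the highest of the other splits was 0 in edgeR, with 135 to 1366 genes at an unadjusted p under 0.05 where the real split had 4197; no other tool was run on them. For the lists 1 of the 10 splits gave as many as the real 25, and the others gave 9 to 23 with 0 genes called. Camera with the preset correlation thus called many lists also under groupings that mixed the siRNAs. The number of list calls therefore hardly sets the real groups apart.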
